A study of Homo sapiens with 44 samples.

How the data were processed

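RNA was sequenced from cells harvested after 0 h, 15 min, 1 h and 2 h in actinomycin D, a drug that blocks transcription, so that the loss of each mRNA over time can be followed. The T cell libraries were made from total RNA, with 3 replicates at each time. The labels say that the T cells came from 3 donors and were stimulated through CD3 and CD28 before the drug was added. The prostate libraries were made from polyadenylated RNA, with 1 library at each time in each of 5 series. These series are PrEC (normal prostate epithelial cells), C4-2 (a prostate cancer cell line), C4-2 treated as a knockdown control, C4-2 with METTL3 knocked down and C4-2 with YTHDF2 knocked down. The methylated RNA immunoprecipitation samples of the same series (PrEC, knockdown control and METTL3 knockdown, 2 input and 2 m6A samples each) were not analysed here.

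The authors deposited 1 table of FPKM values (fragment counts divided by transcript length and by the mapped total of the library), with 28503 rows and 32 columns, all of which matched a labelled sample. Per the submitters' processing notes, the tools named are Trimmomatic, TopHat, Cuffdiff 2.2.1, deepTools, MACS2 and edgeR, and the genome build is hg19. The role of each tool, the annotation, the filters and the handling of strand are not given in the sources used here. FPKM values are relative to the total of their own library, so a fall means a fall against the rest of the library and a rise can mean that an mRNA outlasted the others. No spike-in is named in the labels. Row names were taken from the table, and 22905 of them are a current or older symbol in the reference list of gene names.

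The values are not counts, so no count model was used. FPKM was taken as log2(FPKM + 1), which understates the change of low genes. Genes with a mean FPKM of 1 or more over the libraries of a fit were tested, which gave 11484 genes in T cells and 13052 in the prostate series. Small RNA genes (3245 rows) were left out because FPKM of features shorter than a fragment is unstable; they held 1.39% to 13.9% of a library's FPKM. X-inactivation and Y-linked genes (81 rows) were also left out. Testing used limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, with Benjamini-Hochberg (BH) adjustment over the genes tested and a threshold of 0.05 on the adjusted p. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

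The 12 T cell libraries were fitted with time as a factor, which leaves 8 residual degrees of freedom. Each later time was set against 0 h, and a slope over hours was taken from the 4 time means. The 20 prostate libraries were fitted together, with a level and a slope for each of the 5 series and 2 curvature terms shared by the series, which also leaves 8 residual degrees of freedom. A level is the mean over the 4 times. Because each prostate time point is 1 library and the labels name no separate cultures, p-values in the prostate series measure the scatter of libraries about the fitted courses and not a spread between cultures. They carry no information on whether a new culture would give the same value, and level differences between series reach low p-values for most genes. The comparisons were PrEC against C4-2, each knockdown against the knockdown control, and, as background, the knockdown control against untransfected C4-2.

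Groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. For each comparison the rule names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold. In T cells they must have all 3 libraries at the later time on one side of the 3 at 0 h. The targeted genes are always named, up to 4 members past the threshold are named per gene list, and where no gene passes the 3 with the smallest p are given as values. Exceptions made after the data were seen are that genes listed at 0 in one library and at 10 FPKM or more in another of the same series are not named, nor are genes whose presence varies between people. Immunoglobulin and T cell receptor segments, unnamed loci and small RNAs were excluded by the rule. A few other genes are given by value for their course over time, and these were chosen after their values were seen. A few genes that meet the rule are not reported here.

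There were 32 gene lists, of which 27 in T cells and 26 in the prostate series had the 5 measured members needed for a set test. Set tests used limma's camera with a preset correlation of 0.01 between genes and, beside it, with an estimated correlation, BH-adjusted over the lists of a comparison. The list of zinc finger genes was made by symbol (ZNF and a number). It was meant for KRAB-domain repressors, and some members that moved, such as ZNF217 and ZNF703, are not of that class, so it is called the ZNF-numbered genes. The tumour suppressor list shares 7 genes with the immediate early list.

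The replicate numbers of the T cell labels were checked for pairing. Deviations from the time point means correlated between libraries with the same number (r across genes from 0.588 to 0.805 over 18 pairs) and not between those with other numbers (-0.568 to -0.104 over 36 pairs). The numbers therefore pair the libraries, and the fit with the replicate number as a block is given beside a result where it changes a call or moves a count by over 1.5 times. Libraries were also checked for duplicates, and no pair shared more than 0.00702% of identical values above 0. T cell replicates correlated across genes with r from 0.965 to 0.981 within a time point.

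The read depth is not stated. Steps between low FPKM values gave a relative depth of 0.955 to 1.18 times that of the C4-2 0 h library in the prostate series and of 1 to 1.64 times that of a 0 h library in T cells. Absolute depth and counting intervals are not known. On simulated data with 100 changed genes of each size, the T cell 2 h fit recovered 75% of changes of 1 log2 and 9% of changes of 0.5. The simulated PrEC slope fit recovered 99% of slopes of 0.5 per hour and 51% of slopes of 0.25, and the METTL3 knockdown slope contrast recovered 82% and 16%.

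The alternatives were a pseudocount of 0.1, no filter on low values, a filter at a mean FPKM of 5, quantile normalization, scaling to the median of the ribosomal protein genes, straight lines without curvature, a fit over the 8 libraries of PrEC and C4-2, a fit over the 12 libraries of the knockdown experiment, the replicate block, and leaving out each replicate or time point. Alternatives added after the data were seen were a term for the 6 libraries with high mitochondrial values, leaving out genes with gaps in a series, leaving out the knockdown control 1 h library, and the tumour suppressor list without its immediate early members. The 2 scalings move the median of all genes. On the log2 scale the shift was 0.23 at 1 h, 0.46 at 2 h and 0.23 per hour for the slope in T cells under quantile normalization. Under ribosomal protein scaling it was -0.12, -0.34 and -0.57 at 15 min, 1 h and 2 h and -0.28 per hour. Ribosomal protein scaling also shifted the PrEC slope by -0.12, the YTHDF2 knockdown slope by 0.12, the PrEC minus C4-2 level by 0.33, the METTL3 knockdown level by -0.14 and the level of the knockdown control against C4-2 by -0.28. Quantile normalization shifted the PrEC minus C4-2 level by 0.15 and the YTHDF2 knockdown level by 0.11. Comparisons of a list with the other genes of the same fit are relative to such shifts.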

Results

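Transcript levels were measured by RNA sequencing in human T cells, PrEC and C4-2 cells after transcription was stopped with actinomycin D, so that the rate at which each mRNA was lost could be compared between genes and between cells. The table analysed holds 12 T cell libraries (4 time points, 3 replicates each) and 20 prostate libraries (5 series of 4 time points, 1 library each). METTL3 is the catalytic subunit of the enzyme that writes N6-methyladenosine (m6A) into mRNA, and YTHDF2 is a reader of m6A that recruits the machinery of mRNA decay. The summed FPKM of a library ranged from 521950 to 860328. Absolute read depth is unknown, so no counting interval can be given. The median standard deviation of a gene between T cell replicates was 0.17 on the log2 scale at 0 h, 0.19 at 15 min, 0.19 at 1 h and 0.22 at 2 h. Changes are log2(FPKM + 1) differences with their standard error (SE), and adjusted p-values are from limma with BH adjustment, or from limma's camera for gene lists.

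The targeted genes were lowered in the series named for them. METTL3 averaged 20.7 ± 1.39 FPKM (SD over the 4 libraries of a series) in the knockdown control and 3.91 ± 0.203 FPKM in the METTL3 knockdown, a log2 change of -2.14 (SE 0.06, adjusted p = 7.9e-12). YTHDF2 averaged 50.9 ± 13.6 FPKM in the control and 9.12 ± 3.61 FPKM in the YTHDF2 knockdown, a log2 change of -2.40 (SE 0.05, adjusted p = 2.3e-12). METTL3 was also lower in the YTHDF2 knockdown, at 11.4 ± 0.821 FPKM (-0.81, adjusted p = 1.6e-08). Averaged over the course, YTHDF2 was lower in the METTL3 knockdown, at 42.2 ± 3.32 FPKM (-0.22, adjusted p = 0.0024). Its slope there was higher than in the control by 0.40 per hour (limma, adjusted p = 0.0034), so the difference changed over time. YTHDF2 ranged from 38.1 to 46.1 FPKM in the METTL3 knockdown and from 31.7 to 61.9 FPKM in the control. In untransfected C4-2 the means were 20.2 ± 2.73 FPKM for METTL3 and 48.3 ± 14.2 FPKM for YTHDF2, and in PrEC 19.3 ± 1.06 and 28.4 ± 6.94 FPKM. The wide SD of YTHDF2 reflects its own loss in actinomycin D, with slopes of -0.41 per hour in PrEC (adjusted p = 2.8e-05) and -0.52 in C4-2 (adjusted p = 5.5e-06).

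**Figure D1:**
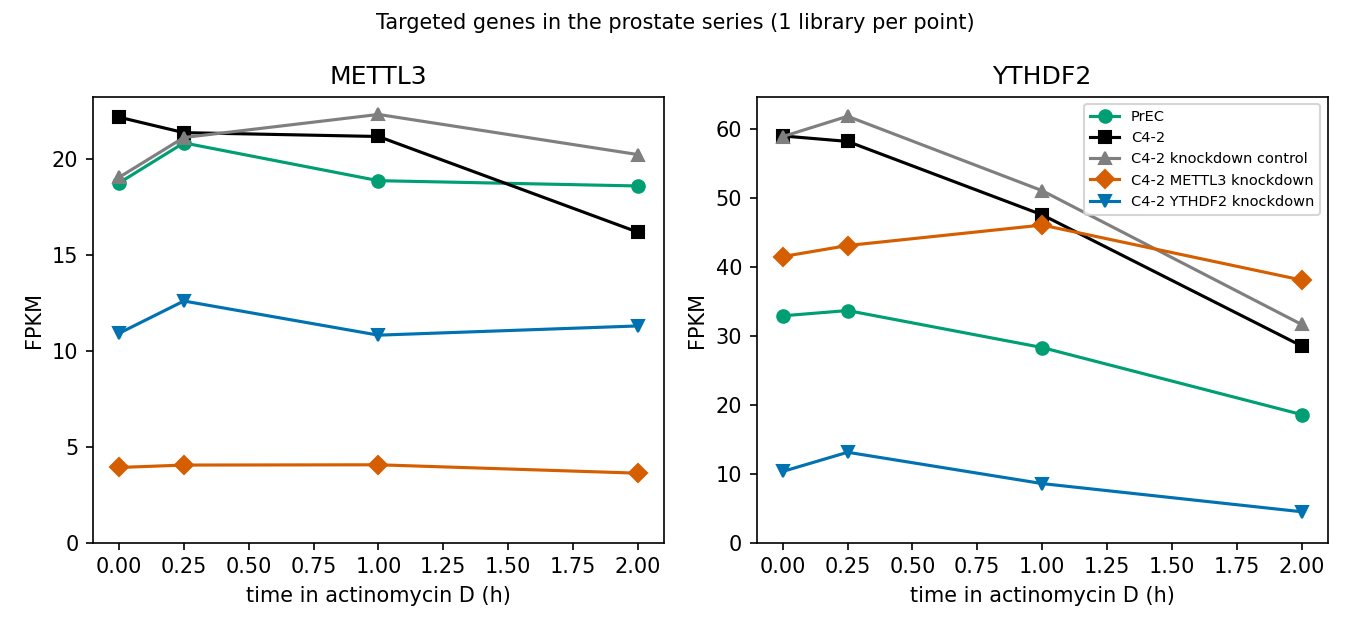
FPKM of METTL3 and YTHDF2 (vertical axes) against time in actinomycin D (hours) in the 5 prostate series, with 1 library per point and no error bars. METTL3 stays near 4 FPKM in the METTL3 knockdown against about 20 in the control, and YTHDF2 is lowest in the YTHDF2 knockdown at every time.

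In T cells, the genes with the largest falls after 15 min included a cytokine and an early activation gene. OSM, a cytokine of the IL-6 family, fell by 2.50 (SE 0.32, adjusted p = 0.0042), and CD69, an early activation antigen, fell by 1.53 (SE 0.15, adjusted p = 0.0013). The other genes with the largest falls were TNF (-1.92), PDE4B (-1.81), SOCS3 (-1.77), ZC3H12A (-1.59), ZFP36L2 (-1.58), KLF2 (-1.55), ZNF217 (-1.52) and TIPARP (-1.51). Of 33 measured immediate early genes, which are induced within minutes of a stimulus, 12 fell and 21 did not pass, with a median of -0.97 against -0.04 for the other genes. Their set test gave an adjusted p of 5.3e-32 and of 0.0019 with an estimated correlation, and 23 fell when adjusted over the list alone. Of 90 tumour suppressors, 7 fell and none rose, among them PRDM1 (-1.40), KLF6 (-1.35), TNFAIP3 (-1.12) and KLF10 (-1.07). Their median was -0.23 (adjusted p = 2e-09, but adjusted p = 0.10 with an estimated correlation), and 12 fell when adjusted over the list alone. In all, 0 genes rose and 102 fell (limma, 950 genes at an unadjusted p under 0.05). Genes with all 3 libraries above those at 0 h numbered 286 and with all 3 below 1384, which is 14.5% of the genes. Chance gives 10% for unpaired libraries, and the share for libraries paired by replicate number was not worked out.

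The 15 min count depended on the fit and on the replicates taken. It was 660 (138 rose, 522 fell) with the replicate number as a block, which uses the pairing of the libraries. In fits without the block it was 23, 0 and 4 without replicate 1, 2 and 3. Those fits hold fewer libraries and ignore the pairing, and leaving out a replicate was not run with the block. Also without the block, the count was 42 with a pseudocount of 0.1 and 39 with a mean FPKM of 5 or more. It was 54 under quantile normalization and 174 under ribosomal protein scaling. In the blocked fit 19 tumour suppressors, 24 immediate early genes and 72 ZNF-numbered genes fell (1 ZNF-numbered gene rose), and 19 ribosomal protein genes and 5 OXPHOS genes rose. The block also added a set call at 15 min for cytokines and chemokines (8 fell and 1 rose, adjusted p = 8.9e-05, and 0.048 with an estimated correlation). Set calls added by the block and lost again with an estimated correlation were those of monocyte markers (adjusted p = 0.0060), unfolded protein and ATF4 genes (0.012), hypoxia genes (0.017) and NK cell markers (0.018), with adjusted p = 0.077, 0.37, 0.45 and 0.15 with an estimated correlation.

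After 2 h the genes with the largest falls were far below their starting level. CISH, an inhibitor of cytokine receptor signalling, averaged 335 ± 55.6 FPKM (SD, n = 3) at 0 h and 6.05 ± 0.728 FPKM at 2 h, a log2 change of -5.57 (SE 0.18, adjusted p = 2.2e-08). KLF2, a transcription factor of resting T cells, went from 215 ± 5.07 to 8.37 ± 2.57 FPKM (-4.56, SE 0.19, adjusted p = 7.2e-08), and NFKBIA, the inhibitor of NF-kB, from 78.0 ± 10.6 to 4.03 ± 0.238 FPKM (-3.97, SE 0.13, adjusted p = 3.2e-08). RHOH (-4.18), OSM (-3.98), SLA (-3.93), SOCS1 (-3.77), BHLHE40 (-3.76), DDIT4 (-3.72) and CD69 (-3.55) completed the 10 largest falls. At 1 h the largest were CISH (-4.69), KLF2 (-4.08), OSM (-3.97), RHOH (-3.77), NFKBIA (-3.50), BHLHE40 (-3.33), DDIT4 (-3.28), PLEKHF1 (-3.21), SOCS1 (-3.20) and MYC (-3.19), and the largest rises were LINC00338 (1.60), ZASP (1.23), RDH5 (1.14), SYCE1L (1.07), GAS6-AS1 (1.06), SNURF (0.99), LENG8 (0.95), MYO15B (0.95), LINC00875 (0.94) and ARHGAP33 (0.92). The genes with the largest rise at 2 h were RPS17L (2.55, SE 0.98, adjusted p = 0.047), LINC00338 (1.59), TMEM110-MUSTN1 (1.53), SNHG9 (1.37, SE 0.25, adjusted p = 0.00070), GAS6-AS1 (1.24), C17orf65 (1.23), MFI2-AS1 (1.22), RDH5 (1.18), SYCE1L (1.17) and LGALS4 (1.11). RPS17L is a copy of another ribosomal protein gene, and the readthrough and antisense genes overlap others, so their values are uncertain while the handling of strand and shared reads is not known.

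At 2 h 773 genes rose and 5101 fell, 2417 of them by more than 1 log2 in either direction; with the replicate block 1776 rose and 6430 fell, and without replicate 2 the rises were 366. The 1 h comparison gave 416 and 2938, or 1630 and 4569 with the replicate block, and 275, 77 and 223 rises without replicate 1, 2 and 3. Genes separated from 0 h in all 3 libraries were 937 above and 4038 below at 1 h (43.3%) and 1015 above and 5447 below at 2 h (56.3%), where chance gives 10% for unpaired libraries. The split between directions depends on the scaling. It was 2582 and 2485 at 2 h and 991 and 1467 at 1 h under quantile normalization, and 11 and 8748 at 2 h and 16 and 5832 at 1 h under ribosomal protein scaling. The 1 h total was 2164 with a mean FPKM of 5 or more and 1562 without replicate 2.

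Of the 90 tumour suppressors measured in T cells, 70 fell at 2 h, 2 rose and 18 did not pass, with a median of -1.03 against -0.35 for the other genes. The adjusted p of the set was 9.1e-07, but adjusted p = 0.16 with an estimated correlation, and 2 rose and 71 fell when adjusted over the list alone. SOCS1 (-3.77), GADD45B (-2.99), a stress-induced growth arrest gene, DUSP6 (-2.93), a phosphatase of the MAP kinase ERK, and PRDM1 (-2.86) changed most. At 1 h 50 fell and none rose (67 and 2 in the blocked fit), with a median of -0.62 (adjusted p = 2.7e-08, and adjusted p = 0.10 with an estimated correlation). Of 56 oncogenes, 29 fell and 2 rose at 2 h, with a median of -0.47 that the set test did not separate from the other genes (adjusted p = 0.32); with the block 34 fell and 5 rose. Under quantile normalization the tumour suppressors had a median of -0.53 at 2 h against 0.10 for the other genes, and under ribosomal protein scaling -1.62 against -0.92.

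Regulatory genes of other kinds fell as well. All 33 immediate early genes fell at 2 h, with a median of -1.81 (adjusted p = 1e-07, but adjusted p = 0.11 with an estimated correlation), led by KLF2 (-4.56), MYC (-3.45), DUSP5 (-3.33) and ZFP36L2 (-3.31). At 1 h 30 fell, with an adjusted p of 0.031 with an estimated correlation that became 0.083 in the blocked fit. Of 303 ZNF-numbered genes, 227 fell and 3 rose at 2 h (259 and 6 with the block; median -0.94, adjusted p = 3.1e-09, and adjusted p = 0.33 with an estimated correlation). Of 19 NF-kB feedback genes 17 fell and none rose, including BCL3 (-3.14) and ICAM1 (-2.53); the set's adjusted p was 0.00088, and 0.14 with an estimated correlation. Among 51 mRNA decay factors 40 fell and none rose, including BTG1 (-2.84; 47 fell and 1 rose with the block), with adjusted p = 9.7e-06 and adjusted p = 0.13 with an estimated correlation. Among 18 m6A writers, readers and erasers 14 fell and 2 rose, led by YTHDF2 (-2.75), CBLL1 (-2.27) and YTHDF1 (-2.20), with adjusted p = 0.0032 and adjusted p = 0.14 with an estimated correlation. Of 30 G2/M phase genes 24 fell and 1 rose, with AURKA (-2.14) and PLK1 (-1.75) among them (adjusted p = 0.018, and adjusted p = 0.79 with an estimated correlation).

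Genes of translation and respiration moved the other way relative to their libraries. At 2 h, 74 of 75 ribosomal protein genes rose and none fell, with a median of 0.67 and with RPL13 at 371 ± 20.1 FPKM at 0 h and 701 ± 39.5 FPKM at 2 h (SD, n = 3). The set's adjusted p was 2.3e-47, but adjusted p = 0.085 with an estimated correlation, and scaling to these genes removes the rise by construction. Of 58 nuclear OXPHOS genes, which code for the respiratory chain, 23 rose and 4 fell (UQCRQ 0.79, ATP5D 0.78, UQCRFS1 -0.81), with a median of 0.32, adjusted p = 1.5e-13 and adjusted p = 0.24 with an estimated correlation. Housekeeping genes (5 rose and 4 fell of 30, adjusted p = 0.00017), glycolysis genes (2 rose and 3 fell of 18, adjusted p = 0.0014), replication-dependent histones (2 rose and none fell of 35, adjusted p = 0.00010) and nuclear long noncoding RNAs (5 rose and 4 fell of 18, adjusted p = 0.0050) also had medians above the other genes. With an estimated correlation their adjusted p-values were 0.32, 0.50, 0.26 and 0.26. The replicate block moved these counts at 2 h: 38 OXPHOS genes rose and 8 fell, 15 and 7 housekeeping genes, 13 and 4 glycolysis genes, 4 and 0 histones, and 9 and 5 long noncoding RNAs. Under ribosomal protein scaling the direction of the OXPHOS genes turned (median -0.36, 0 rose and 28 fell), as did that of the housekeeping, glycolysis, histone and long noncoding RNA lists.

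The sets of T cell markers, T cell activation genes and cytokines were not separated from the other genes at 2 h. T cell markers gave 3 higher and 9 lower of 20 (adjusted p = 0.64) and T cell activation genes 1 and 15 of 25 (adjusted p = 0.26, median -1.06). Cytokines and chemokines gave 0 and 8 of 26 (adjusted p = 0.69). Without the block, NK cell markers had no member past the threshold of 12 measured but a median of 0.19 (adjusted p = 0.027, and adjusted p = 0.42 with an estimated correlation; this direction turned under ribosomal protein scaling). Nor did any of 7 B cell markers (adjusted p = 0.16) or 5 monocyte markers (adjusted p = 0.076) pass. The replicate numbers pair these libraries, and with the block 5 NK cell markers were higher and 3 lower at 2 h, 4 monocyte markers higher and none lower, and 2 B cell markers higher and 1 lower. T cell markers were then 7 and 10, T cell activation genes 3 and 18, and cytokines and chemokines 4 and 14.

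With the block the monocyte set had an adjusted p of 0.0010 at 2 h and of 0.0038 at 1 h, but adjusted p = 0.10 and 0.083 with an estimated correlation. At 1 h the block also added set calls for NK cell markers (adjusted p = 0.0022, but adjusted p = 0.083 with an estimated correlation) and T cell activation genes (0.032, but adjusted p = 0.31 with an estimated correlation). S phase genes (2 rose, 12 fell of 32), p53 targets (0 and 16 of 28), interferon-stimulated genes (3 and 18 of 36), cholesterol synthesis genes (1 and 13 of 22), unfolded protein and ATF4 genes (0 and 12 of 25), hypoxia genes (0 and 6 of 15) and androgen receptor targets (0 and 2 of 11) did not differ as sets from the other genes, with adjusted p-values from 0.16 for p53 targets to 0.95 for S phase genes. With the block their counts at 2 h were 4 and 18 for S phase genes, 2 and 20 for p53 targets, 6 and 23 for interferon-stimulated genes, 3 and 13 for cholesterol synthesis genes, 3 and 15 for unfolded protein and ATF4 genes, 1 and 8 for hypoxia genes and 0 and 5 for androgen receptor targets. The few measured members of the luminal prostate (1), basal epithelial (3), fibroblast (4) and red cell and platelet (1) lists did not pass, and no mitochondrially encoded gene was measured.

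**Figure D2:**
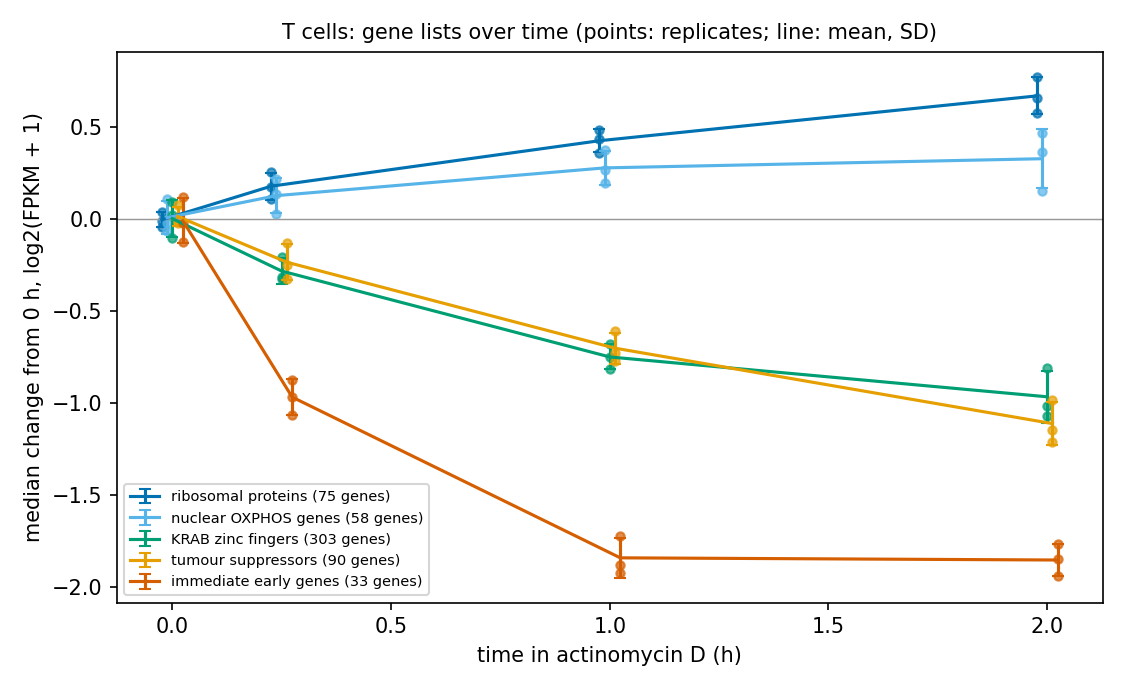
Median log2(FPKM + 1) of the members of 5 gene lists in T cells, relative to 0 h, against time in actinomycin D (hours); points are the 3 replicates, lines join their means and bars are the SD. Immediate early genes reach -1.84 at 1 h, tumour suppressors -1.11 at 2 h and ribosomal protein genes 0.67 at 2 h; under ribosomal protein scaling the OXPHOS genes turn downward.

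Over the whole course, 849 genes had a rising and 5332 a falling slope in T cells, or 2904 and 2657 under quantile normalization and 11 and 8974 under ribosomal protein scaling. With the replicate block 1829 rose and 6582 fell, and without replicate 2 the rising slopes were 449. The steepest were CISH (-2.75 per hour), KLF2 (-2.19), RHOH (-2.03), SLA (-1.97), NFKBIA (-1.90), BHLHE40 (-1.81), FADD (-1.80), DDIT4 (-1.78), TNFRSF1A (-1.77) and SOCS1 (-1.76). The largest rising slopes were those of RPS17L (1.15), LINC00338 (0.81), PHGR1 (0.70), C17orf65 (0.68), SNHG9 (0.63), GAS6-AS1 (0.61), TMEM110-MUSTN1 (0.56), RDH5 (0.55), LGALS4 (0.55) and MFI2-AS1 (0.55). The tumour suppressor list had a median slope of -0.51 against -0.18 for the other genes, with 71 falling and 2 rising of 90 (adjusted p = 1.8e-06, but adjusted p = 0.18 with an estimated correlation; 2 rising and 74 falling when adjusted over the list alone).

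In PrEC, the normal prostate epithelial cells, the fastest losses included those of stress and growth factor response genes. IER3, an early response gene of cell survival, had a slope of -2.87 per hour (SE 0.10, adjusted p = 1.2e-09) and went from 568 FPKM at 0 h to 10.6 FPKM at 2 h. MYC had a slope of -2.71 (SE 0.22, adjusted p = 7.5e-07), and DDIT4 (-2.77), DUSP6 (-2.60), EGR1 (-2.51), ZFP36 (-2.51), FOS (-2.50), JUNB (-2.37), DUSP1 (-2.33) and PLK2 (-2.28) followed. Rising slopes were small, with RPS17L at 1.27, whose reads may be shared with its copy, IFI27 at 0.88 (SE 0.20, adjusted p = 0.0050; its level was 5.48 FPKM at 2 h and at most 1.01 FPKM before), and PGAM2 (0.45), TMEM238 (0.42), PABPC1L (0.41), ENHO (0.41), CHKB-CPT1B (0.41), CHURC1-FNTB (0.37), SRP14-AS1 (0.37) and IL11RA (0.34). Of 95 tumour suppressors 48 fell, 1 rose and 46 did not pass, with a median slope of -0.17 against -0.01 (adjusted p = 1e-08, and 0.032 with an estimated correlation), and 2 rose and 51 fell when adjusted over the list alone. Before adjustment over the lists, the value with an estimated correlation was 0.0012. It was 0.095 under ribosomal protein scaling, where the call was lost, 0.025 with straight lines, 0.018 without the 0 h and 0.020 without the 15 min libraries; adjustment over the lists was not run for these alternatives, so it is open whether the call held in the last 3. Without the 2 h libraries 21 fell and the gap of -0.16 to the other genes was -0.10; with a pseudocount of 0.1 it was -0.25. DUSP6, EGR1, GADD45B (-2.04) and BTG2 (-1.62), an antiproliferative gene, led them. Of 64 oncogenes 17 fell and 8 rose (adjusted p = 0.43).

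Transcription factor and signalling lists fell in PrEC as well. Of 39 immediate early genes 37 fell (median -1.54, adjusted p = 2.6e-24, but adjusted p = 0.11 with an estimated correlation), and of 357 ZNF-numbered genes 255 fell and 1 rose (median -0.36, adjusted p = 5e-27, and 0.035 with an estimated correlation). NF-kB feedback genes gave 9 falls of 18 (adjusted p = 0.0080), p53 targets 15 of 29 with 2 rises (0.0013), m6A genes 12 of 20 (0.0017) and mRNA decay factors 18 of 51 with 1 rise (0.00049). Their adjusted p-values with an estimated correlation were 0.22, 0.11, 0.20 and 0.11. Ribosomal protein genes rose in 65 of 75 cases (median 0.15, adjusted p = 6.1e-22) and OXPHOS genes in 35 of 58 (adjusted p = 1.8e-13), with adjusted p = 0.16 and adjusted p = 0.20 with an estimated correlation. In all, 961 genes had rising and 2731 falling slopes in PrEC. The split was 1618 and 1630 under quantile normalization and 23 and 5230 under ribosomal protein scaling. The total was 579 without the 2 h libraries, and 525 slopes rose without the 0 h libraries.

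In C4-2, NFKBIA had the steepest slope, at -2.53 per hour (SE 0.28, adjusted p = 1.8e-05), from 67.3 FPKM at 0 h to 1.58 FPKM at 2 h. DDIT4 (-2.16), MYC (-2.15), TXNIP (-1.83), an inhibitor of thioredoxin, CITED2 (-1.80), PLK2 (-1.72), HES1 (-1.70), JUN (-1.68) and JUNB (-1.65) came next. YJEFN3 (0.61), S100A1 (0.52), HSF4 (0.50), LTB4R2 (0.49), LY6G5B (0.49), BST2 (0.47), SAP25 (0.46), MUC1 (0.45), HMGN5 (0.44) and LCN12 (0.44) had the largest rising slopes. Of 95 tumour suppressors 48 fell, 2 rose and 45 did not pass, with a median of -0.19 against -0.03 (adjusted p = 1.7e-06, and 0.039 with an estimated correlation; 2 and 52 when adjusted over the list alone), led by BTG2 (-1.50), GADD45B (-1.18), KLF10 (-1.14) and KLF4 (-0.99); without the 2 h libraries 18 fell. The value with an estimated correlation was 0.0030 before adjustment over the lists. The call was lost under ribosomal protein scaling and with straight lines (0.15 and 0.051), and whether it held without the 0 h (0.029) or the 15 min libraries (0.031) is open. Of 64 oncogenes 20 fell and 3 rose (adjusted p = 0.18). Immediate early genes fell in 30 of 39 cases (median -0.87, adjusted p = 1.8e-13, but adjusted p = 0.21 with an estimated correlation), and ZNF-numbered genes in 277 of 357 with 2 rises (median -0.37, adjusted p = 4.7e-30, and 0.039 with an estimated correlation). Unfolded protein and ATF4 genes fell in 13 of 25 cases, with 1 rise (adjusted p = 0.016, and adjusted p = 0.31 with an estimated correlation). Ribosomal protein genes gave 23 rises of 75 (adjusted p = 4.7e-13, but adjusted p = 0.29 with an estimated correlation), a direction that turned under both scalings. There were 679 rising and 2719 falling slopes, 1394 and 1501 under quantile normalization and 72 and 4783 under ribosomal protein scaling. The total was 2120 without the 0 h libraries and 615 without the 2 h libraries.

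**Figure D3:**
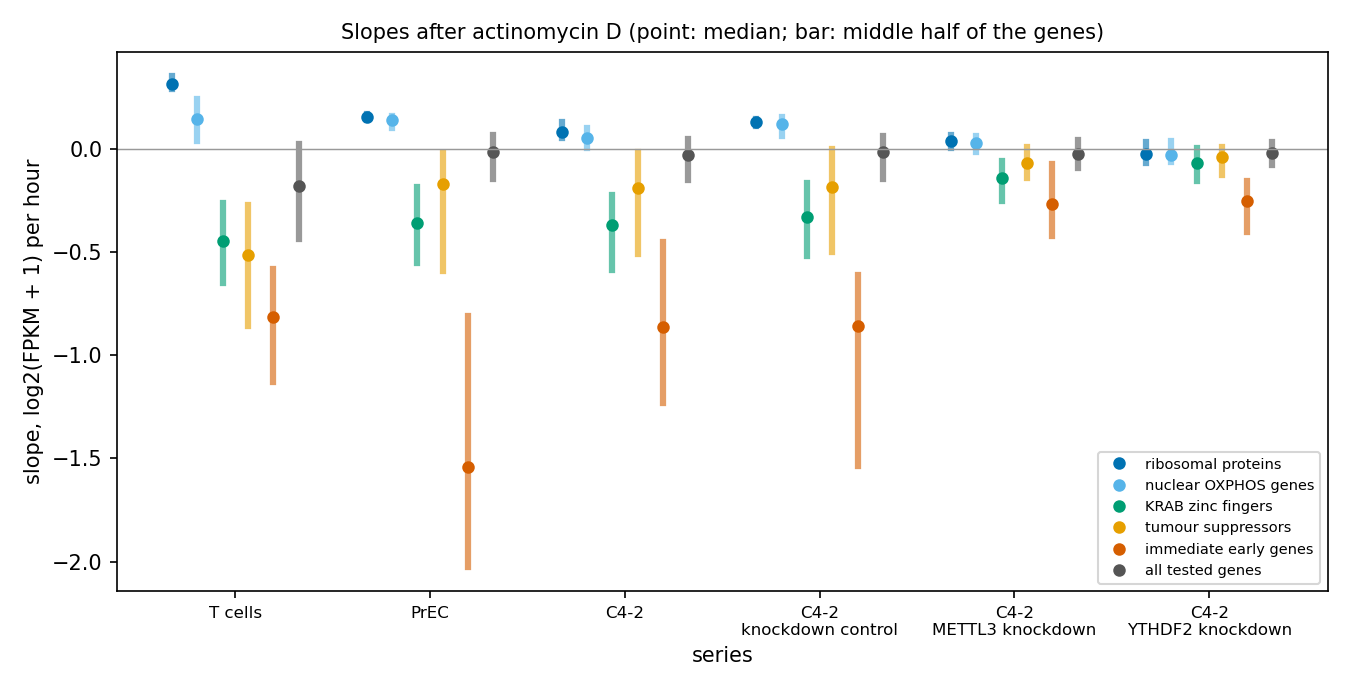
Slope of log2(FPKM + 1) per hour in actinomycin D (vertical axis) for 5 gene lists and all tested genes in T cells and the 5 prostate series; points are medians over genes and bars span the middle 50% of genes, which is not an error between libraries. Immediate early genes have the lowest median in each series, from -1.54 in PrEC to -0.25 in the YTHDF2 knockdown; ribosomal protein and OXPHOS directions turn in some series under other scalings, and the list called KRAB zinc fingers holds the ZNF-numbered genes.

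Slopes were compared across genes between cell types, which per the labels had different doses of actinomycin D (10 ug/ml in T cells and 5 ug/ml in the prostate series). The T cell libraries were also made from total RNA of stimulated cells, and the prostate libraries from polyadenylated RNA. T cell and prostate slopes are therefore not the same measure. Over the 10182 genes tested in both fits, Pearson's r across genes (which are not independent replicates) was 0.67 between T cells and PrEC, 0.64 between T cells and C4-2, 0.79 between PrEC and C4-2, and 0.87 between C4-2 and its knockdown control. It was 0.61 between the control and the METTL3 knockdown and 0.36 between the control and the YTHDF2 knockdown. By rank (Spearman) the values were 0.73 for T cells and PrEC, 0.64 for T cells and C4-2, 0.70 for PrEC and C4-2 and 0.74 for C4-2 and its control. They were 0.53 and 0.20 for the control with the METTL3 and the YTHDF2 knockdown. PrEC and C4-2 slopes come from 1 fit with shared curvature terms. Falling slopes in T cells, PrEC and C4-2 alike were found for 1511 genes, where 238 would fall in all 3 if the lists were independent. These included 37 tumour suppressors, 24 immediate early genes and 183 ZNF-numbered genes; among the tumour suppressors were the chromatin regulators ARID1A, KMT2D and CREBBP and the growth inhibitors BTG1, BTG2, TOB1 and CDKN1B, named after the overlap was seen.

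The difference in slope between PrEC and C4-2 was tested itself. Genes with a lower slope in PrEC included early response genes, with IER3 at -2.98 per hour (SE 0.14, adjusted p = 1.3e-07), DUSP6 at -2.48, FOS at -2.42, EGR1 at -2.26, SNAI2 at -1.79, ZFP36 at -1.76, ADM at -1.70, DUSP5 at -1.53, TIPARP at -1.37 and FOXQ1 at -1.35. IER3 started at 568 FPKM in PrEC and at 5.54 FPKM in C4-2, where the scale leaves less room to fall. TXNIP (1.13), DUSP2 (1.01), MIRLET7BHG (0.95), BAMBI (0.92), HLX (0.92), MYLIP (0.88), FAM110B (0.87), TOX3 (0.84), ZIC2 (0.81) and ARC (0.78) had a higher slope in PrEC. Starting levels are not given for the named genes other than IER3. Their differences in slope may therefore come from differences in level and need not be differences in decay. Of 39 immediate early genes 10 had a lower and 2 a higher slope (median -0.45, adjusted p = 3e-10, but adjusted p = 0.62 with an estimated correlation; 4 higher and 17 lower when adjusted over the list alone). Of 95 tumour suppressors 6 were lower, 2 higher and 87 did not pass (median -0.04 against 0.01, adjusted p = 0.020, but adjusted p = 0.55 with an estimated correlation; 5 higher and 9 lower when adjusted over the list alone). DUSP6, EGR1, AXIN2 (0.73) and FOXO1 (-0.65) were the members with the largest difference. In all, 98 genes had a higher and 201 a lower slope in PrEC. This total of 299 was 187 with straight lines, 196 in a fit of these 8 libraries, and 59, 50 and 23 without the 0 h, 15 min and 2 h libraries.

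The levels of PrEC and C4-2 differed for most genes. The basal keratins KRT5 (12.72), KRT17 (12.49), KRT6A (12.04) and KRT14 (10.71) were higher in PrEC, with ANXA2 (11.31), SPRR1B (11.24), S100A6 (11.07), GSTP1 (10.74), S100A2 (10.57) and S100A14 (10.13). The androgen-regulated prostate genes KLK3 (-10.09), which codes for prostate-specific antigen, KLK4 (-7.79) and KLK2 (-7.76) were lower, as were SPON2 (-8.35), FOLH1 (-8.23), EEF1A2 (-8.16), PAGE1 (-8.00), PRKACB (-7.25) and LRRC26 (-6.91). All 20 basal epithelial markers were higher (median 8.51, adjusted p = 3.6e-14, but adjusted p = 0.10 with an estimated correlation), and 13 of 16 luminal markers were lower and 2 higher (median -3.69, adjusted p = 0.0075, but adjusted p = 0.51 with an estimated correlation). Androgen receptor targets were lower in 22 and higher in 5 of 28 cases (adjusted p = 0.0042, and adjusted p = 0.51 with an estimated correlation). All 7 measured fibroblast markers were higher, among them SPARC (5.16) and VIM (4.76), which basal epithelial cells in culture also express (adjusted p = 0.00012, but adjusted p = 0.062 with an estimated correlation), and all 4 measured monocyte markers were higher, among them S100A9 (8.88) and S100A8 (7.99), which keratinocytes also make.

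Cell cycle genes were lower in PrEC than in C4-2, with all 32 S phase genes (median -1.66, adjusted p = 8.7e-06) and 27 of 30 G2/M genes (median -0.99, adjusted p = 0.00062; 1 higher). The adjusted p was 0.49 with an estimated correlation for both. Immediate early genes were higher in 27 and lower in 6 of 39 cases (median 1.45, adjusted p = 9.2e-06, but adjusted p = 0.49 with an estimated correlation). The p53 targets (18 higher, 6 lower of 29, adjusted p = 0.00045) and cholesterol synthesis genes (17 and 5 of 23, adjusted p = 0.00055) were higher and OXPHOS genes lower (4 and 52 of 58, adjusted p = 0.00055), with adjusted p = 0.10, 0.49 and 0.55 with an estimated correlation. Tumour suppressors went both ways, with 35 higher, 53 lower and 7 not passing (adjusted p = 0.47). In all 4011 genes were higher and 7547 lower in PrEC, or 5638 and 5543 under ribosomal protein scaling.

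In the METTL3 knockdown, most immediate early genes were higher than in the knockdown control (30 of 39, adjusted p = 9.1e-07, but adjusted p = 0.97 with an estimated correlation). GADD45B, a stress-induced growth arrest gene, was raised by 3.29 (SE 0.30, adjusted p = 4e-07), and RAB3A (2.44), DUSP1 (2.43), HES1 (2.38), RIPK4 (2.33), ELF3 (2.32), JUND (2.24), MYL9 (2.18) and BHLHE40 (2.15) followed. CCL20, a chemokine, was lower by -3.46 (SE 0.12, adjusted p = 9.7e-11), with SLC7A11 (-3.09), LCN2 (-2.89), SDCBP2 (-2.78), HNRNPM (-2.41), DOK3 (-2.37), ATF5 (-2.35), NCOA5 (-2.30) and C11orf92 (-2.29). Of the immediate early genes 1 was lower and 8 did not pass, with a median of 1.01 over the course and of 0.38 at 0 h. All 32 S phase genes (median -0.996, adjusted p = 1.2e-09) and 29 of 30 G2/M genes (median -0.96, adjusted p = 1.1e-09) were lower, with PLK1 at -1.58 and CDC20 at -1.43. Ribosomal protein genes (49 higher, 5 lower of 75, adjusted p = 7.1e-05), OXPHOS genes (38 and 5 of 58, adjusted p = 7.3e-05) and cholesterol synthesis genes (13 and 2 of 23, adjusted p = 0.027) were higher. Each of these 6 sets had an adjusted p of 0.97 with an estimated correlation, and the ribosomal direction turned when libraries were scaled to these genes. Tumour suppressors were higher in 33, lower in 31 and not past the threshold in 31 cases (adjusted p = 0.92), with GADD45A at 1.81 and KLF6 at 1.74; their gap of 0.04 to the other genes was -0.0066 without the 2 h libraries and 0.07 without the 15 min libraries. In all 4266 genes were higher and 5053 lower, or 4813 and 4636 under quantile normalization and 2726 and 6450 under ribosomal protein scaling. Basal keratins such as KRT5 (-1.36) were lower against a control whose 1 h library held 5.83 FPKM of KRT5, 0.0863% of the PrEC mean. The control held 0.674, 0.622 and 1.34 FPKM of KRT5 at 0 h, 15 min and 2 h, so its 1 h library weighs on this change. KRT5 was listed at 0 FPKM at every time in the METTL3 knockdown and in untransfected C4-2. The change therefore rests on the values of the control and need not be an effect of the knockdown.

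Short-lived mRNAs lost less over time in the METTL3 knockdown than in its control. DDIT4, a stress-induced inhibitor of mTOR signalling, had a slope higher by 2.13 per hour (SE 0.28, adjusted p = 0.00049). At 2 h 37.9% of its starting FPKM remained in the knockdown and 1.86% in the control. CHAC1 (1.85), TXNIP (1.77), BHLHE40 (1.63), ID1 (1.56), CITED2 (1.56), JUNB (1.51), PLK2 (1.42) and BAMBI (1.35) also had higher slopes. The lower slopes were small, with LUST (-0.62), TPM2 (-0.60), WASH5P (-0.55), HIST1H2AG (-0.48, which is 0.04 without the 2 h libraries), GABBR1 (-0.47), GOLGA8A (-0.47), GOLGA8B (-0.45), GPHA2 (-0.45), SERPINB8 (-0.44) and C1orf145 (-0.44). GOLGA8A and GOLGA8B are near-identical copies whose values are uncertain. Of 95 tumour suppressors 29 had a higher slope, none a lower one and 66 did not pass (median 0.13 against 0.00, adjusted p = 4.1e-07, but adjusted p = 0.062 with an estimated correlation; 33 when adjusted over the list alone), with BTG2 (1.25), KLF10 (1.17), GADD45A (1.08) and TOB1 (1.00) in front. This list had 9, 14 and 9 higher slopes without the 0 h, 15 min and 2 h libraries. Its gap of 0.12 to the other genes was 0.20 without the 2 h libraries and 0.08 with a term for the 6 libraries whose mitochondrial values are above 0. Of 39 immediate early genes 18 were higher and 21 did not pass (median 0.65, adjusted p = 1.1e-15), and of 357 ZNF-numbered genes 64 were higher (adjusted p = 6.2e-13); both had adjusted p = 0.17 with an estimated correlation. NF-kB feedback genes (4 of 18, adjusted p = 0.00075), p53 targets (7 of 29, 0.0019) and mRNA decay factors (10 of 51, 0.0019) had higher slopes too, with adjusted p = 0.17 with an estimated correlation in each. Ribosomal protein genes had a median of -0.09 with no member past the threshold (adjusted p = 9.4e-11, but adjusted p = 0.39 with an estimated correlation), and this sign turned under both scalings. In all 986 slopes were higher and 69 lower, or 751 and 189 under quantile normalization and 1460 and 12 under ribosomal protein scaling. The total of 1055 was 676 with straight lines and 271, 404 and 135 without the 0 h, 15 min and 2 h libraries. Lower slopes numbered 42 without the 1 h libraries, 24 with straight lines and 34 in the fit over the 12 knockdown experiment libraries (743 in total).

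In the YTHDF2 knockdown the same control was used. GADD45B was higher by 4.38 (SE 0.30, adjusted p = 1.6e-08), with HES1 (3.52), CYR61 (3.26), RASD1 (3.09), NR1D1 (3.06), JUNB (2.98), ATF3 (2.97), PER1 (2.95), HMOX1 (2.95) and DUSP1 (2.80). Here too a level is the mean over the course, to which a slower loss adds, and differences at 0 h are not given for these genes. CCL20 (-3.49), CHST2 (-3.14), SDCBP2 (-3.06), ADI1 (-2.96), RRM2 (-2.86), LCN2 (-2.65), MAP4K4 (-2.59), MAF (-2.59) and NCOA5 (-2.50) were lower. CHST2 was itself higher in the control than in untransfected C4-2, by 3.79, so its lower level here need not come from the knockdown. That comparison is not given for the other genes of this list. Immediate early genes were higher in 32 and lower in 1 of 39 cases (median 1.59, and 0.82 at 0 h, adjusted p = 5e-10), S phase genes lower in 29 and higher in 1 of 32 (median -0.94, adjusted p = 3.9e-06) and G2/M genes lower in 29 of 30 (median -1.11, adjusted p = 3.1e-08), with adjusted p-values of 0.48, 0.53 and 0.48 with an estimated correlation. The other YTHDF readers were lower as well, YTHDF3 by -1.43 and YTHDF1 by -1.39; of the 20 m6A genes 12 were higher and 8 lower. Interferon-stimulated genes were lower in 22 and higher in 1 of 30 cases (adjusted p = 0.043), and histones (12 higher, 2 lower of 24, 0.018), p53 targets (17 and 8 of 29, 0.012) and nuclear long noncoding RNAs (10 and 1 of 18, 0.012) were higher, with adjusted p = 0.53, 0.48, 0.48 and 0.53 with an estimated correlation. Tumour suppressors were higher in 40, lower in 35 and not past the threshold in 20 cases. Their median was 0.03 over the course and -0.16 at 0 h, against -0.11 for the other genes over the course (adjusted p = 0.11 over the lists, and adjusted p = 0.53 with an estimated correlation). The gap of 0.15 was 0.26 without the 0 h libraries and 0.06 without the filter on low values. In all 3940 genes were higher and 6110 lower, or 4942 and 5101 under quantile normalization.

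Slopes in the YTHDF2 knockdown were likewise less negative for short-lived mRNAs. TXNIP was higher by 2.14 per hour (SE 0.24, adjusted p = 9.8e-05), with 54.5% of its starting FPKM left at 2 h against 2.82% in the control. DDIT4 (1.90), CHAC1 (1.86), BTG2 (1.80), CITED2 (1.80), PLK2 (1.72), BHLHE40 (1.64), BAMBI (1.54) and KLF10 (1.45) were next. PRR5-ARHGAP8 (-0.79), SLURP1 (-0.74), BLOC1S1-RDH5 (-0.71), YJEFN3 (-0.63), PAQR6 (-0.63), PAM (-0.60), CPT1B (-0.60), TPM2 (-0.58), ENO3 (-0.56) and FBXL8 (-0.56) had lower slopes, and the hyphenated readthrough genes overlap their neighbours. Of 95 tumour suppressors 33 were higher, none lower and 62 did not pass (median 0.19 against 0.01, adjusted p = 2e-06, but adjusted p = 0.086 with an estimated correlation; 41 higher and 4 lower when adjusted over the list alone). BTG2, KLF10, TOB1 (1.14), which codes for an antiproliferative partner of the deadenylase complex, and GADD45A (1.09) led. The list had 17 and 13 higher slopes without the 0 h and 2 h libraries. With the term for the 6 libraries whose mitochondrial values are above 0 it had 18, and its gap to the other genes went from 0.18 to 0.08. Immediate early genes were higher in 19 of 39 cases (median 0.60, adjusted p = 1.9e-11, but adjusted p = 0.24 with an estimated correlation), ZNF-numbered genes in 131 of 357 (adjusted p = 5.8e-17, but adjusted p = 0.12 with an estimated correlation) and NF-kB feedback genes in 7 of 18 (adjusted p = 0.0019, but adjusted p = 0.23 with an estimated correlation), among them NFKBIA (1.34). Ribosomal protein genes were lower in 26 of 75 cases (adjusted p = 1.7e-14) and OXPHOS genes in 11 of 58 (adjusted p = 5.2e-09), with adjusted p = 0.32 and adjusted p = 0.36 with an estimated correlation. The ribosomal direction turned under quantile normalization and the OXPHOS direction under ribosomal protein scaling.

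In all 1519 slopes were higher and 468 lower in the YTHDF2 knockdown, or 1169 and 619 under quantile normalization and 3078 and 44 under ribosomal protein scaling. The total of 1987 was 712, 1089 and 310 without the 0 h, 15 min and 2 h libraries, and 284 slopes were lower without the 1 h libraries. Lower slopes numbered 247 with straight lines and 251 in the fit over the 12 knockdown experiment libraries. It was 643 with a term for the 6 libraries whose mitochondrial values are above 0. These 6 include the control at 1 h and 2 h and the YTHDF2 knockdown at 0 h, so that term is confounded with this slope difference. Within single series, falling slopes numbered 2795 in the knockdown control (822 rising), 505 in the METTL3 knockdown (100 rising) and 178 in the YTHDF2 knockdown (56 rising).

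**Figure D4:**
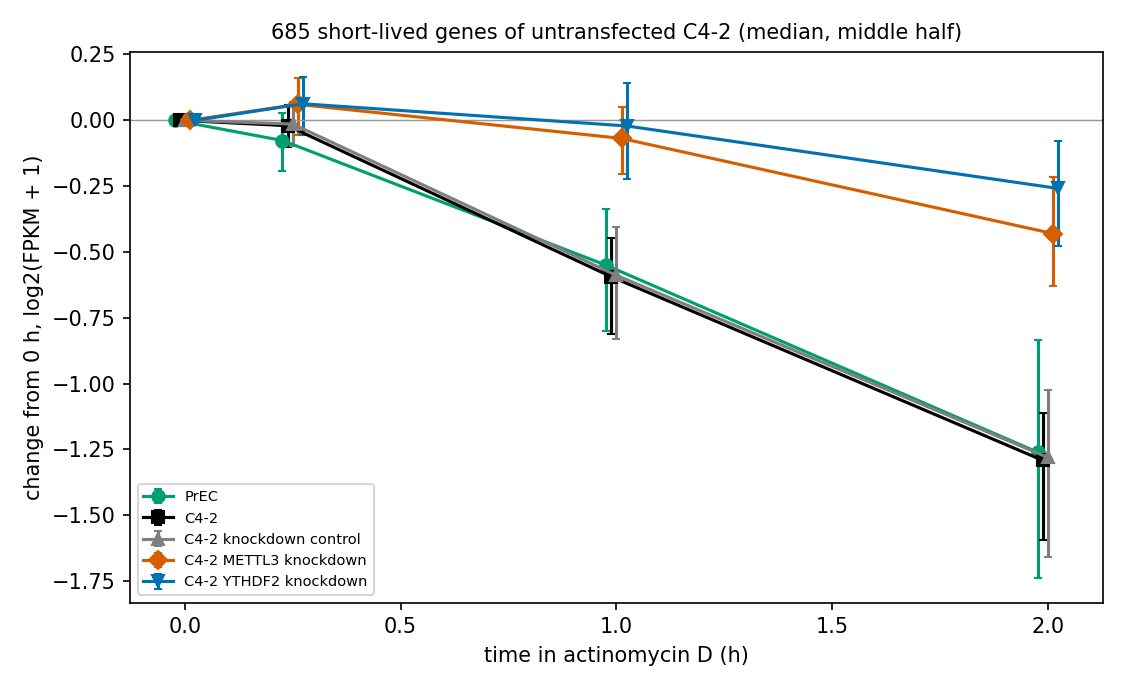
Change of log2(FPKM + 1) from 0 h (vertical axis) against time in actinomycin D (hours) for the 685 genes with a slope of -0.5 per hour or lower in untransfected C4-2; points are medians over genes and bars span the middle 50% of genes, with 1 library per time. At 2 h the medians are -1.26 in PrEC, -1.29 in C4-2 and -1.28 in the control, but -0.43 in the METTL3 knockdown and -0.26 in the YTHDF2 knockdown; C4-2 was used to choose the genes.

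Both knockdowns were set against the same 4 control libraries, so their changes share chance values. The level changes correlated across genes with r = 0.736, where unchanged groups simulated with a shared control gave 0.503 (SD 0.0720 over 100 simulations). The covariance was 0.258 against a simulated 0.00448, and r was 0.708 and 0.695 with the control libraries split between the comparisons. For slope changes r was 0.878 against a simulated 0.501, the covariance 0.0724 against 0.00748, and the split values 0.627 and 0.674. Genes with a higher slope in both numbered 850, where independent lists would share 115, and those with a lower slope 35, where independent lists would share 2.47. For levels 2687 genes were higher in both (independent 1288) and 4002 lower in both (independent 2365). Part of each excess may come from the shared controls. The split controls are times of 1 series, and the simulation drew only scatter about the fit. Neither covers a deviation of the control series itself, which would move both knockdown comparisons alike.

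The knockdown control and untransfected C4-2 show how far series without a knockdown differ. The genes with the largest rise in the control included hypoxia-induced genes such as VEGFA, with NDUFA4L2 at 4.10 (SE 0.17), CHST2 at 3.79, CYP4F8 at 3.67, PLOD2 at 2.74, TSC22D3 at 2.70, CHAC1 at 2.67, IGFBP3 at 2.64, ENO2 at 2.49, GDF15 at 2.48 and VEGFA at 2.44. Proliferation genes were lower, with AURKA at -2.53, SKA3 at -2.20, FAM111B at -2.06, MDC1 at -1.99, UBE2C at -1.96, MCM10 at -1.96, MKI67 at -1.95, FOXM1 at -1.94 and CCNA2 at -1.93, beside the transporter SLC22A3 at -2.81. All 30 G2/M genes (median -1.66, adjusted p = 2.2e-18) and 31 of 32 S phase genes (median -1.44, adjusted p = 1.4e-16) were lower, and 18 of 19 hypoxia genes (median 1.12, adjusted p = 1e-06) and 24 of 29 p53 targets (1 lower, adjusted p = 9.7e-07) were higher. With an estimated correlation the adjusted p-values were 0.15, 0.26, 0.26 and 0.063. Ribosomal protein genes were higher in 65 and lower in 2 of 75 cases (adjusted p = 2.5e-09), glycolysis genes in 15 and 2 of 18 (0.0071), unfolded protein and ATF4 genes in 16 and 6 of 25 (0.024) and histones in 17 and 6 of 24 (0.035). Cholesterol synthesis genes were lower in 15 of 23 cases (0.0021) and decay factors in 27 of 51 with 11 higher (0.018). With an estimated correlation these 6 adjusted p-values were 0.47, 0.57, 0.44, 0.41, 0.50 and 0.32. In all 5116 genes were higher and 4204 lower, or 4410 and 4700 under quantile normalization and 2483 and 7121 under ribosomal protein scaling. METTL3 differed by 0.04 (adjusted p = 0.56) and YTHDF2 by 0.08 (adjusted p = 0.19).

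In slope, no gene passed between these 2 series (limma, 1169 genes at an unadjusted p under 0.05). The smallest p-values belonged to ALAS1 (-0.44 per hour, adjusted p = 0.090), BTG2 (-0.58, adjusted p = 0.090) and DDX10 (-0.44, adjusted p = 0.13). The count was 2 without the filter on low values and 2 with a mean FPKM of 5 or more, 4 under quantile normalization and 7 without the 1 h libraries. No list had a member past the threshold, and immediate early genes had a median of -0.12 (adjusted p = 0.0028, but adjusted p = 0.96 with an estimated correlation). On simulated data, this contrast recovered 87% of slope differences of 0.5 per hour and 24% of differences of 0.25.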

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

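Of the tests in this part, the splits of the samples were planned, and the tests of the 3 explanations and the centred splits were chosen after the result was seen. The results below stand out because the loss of mRNA differed between series in a test of the difference itself, with 1 library per time point and series.

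Between PrEC and C4-2, 299 slopes differed and the tumour suppressor list had a median difference of -0.038. The genes were TXNIP 1.13, DUSP2 1.01, MIRLET7BHG 0.95, BAMBI 0.92, HLX 0.92, MYLIP 0.88, FAM110B 0.87, TOX3 0.84, ZIC2 0.81, ARC 0.78, IER3 -2.98, DUSP6 -2.48, FOS -2.42, EGR1 -2.26, SNAI2 -1.79, ZFP36 -1.76, ADM -1.70, DUSP5 -1.53, TIPARP -1.37 and FOXQ1 -1.35 per hour. The count was 23 without the 2 h libraries, 50 without 15 min and 59 without 0 h. The difference was not weighed further.

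Between the METTL3 knockdown and its control, 1055 slopes differed and the tumour suppressor list had a median difference of 0.13. The genes were DDIT4 2.13, CHAC1 1.85, TXNIP 1.77, BHLHE40 1.63, ID1 1.56, CITED2 1.56, JUNB 1.51, PLK2 1.42, BAMBI 1.35, LUST -0.62, TPM2 -0.60, WASH5P -0.55, HIST1H2AG -0.48, GABBR1 -0.47, GOLGA8A -0.47, GOLGA8B -0.45, GPHA2 -0.45, SERPINB8 -0.44 and C1orf145 -0.44 per hour. The count was 135 without the 2 h libraries, 404 without 15 min and 271 without 0 h, and HIST1H2AG was 0.04 without the 2 h libraries.

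Between the YTHDF2 knockdown and the control, 1987 slopes differed and the tumour suppressor list had a median difference of 0.19. The genes were TXNIP 2.14, DDIT4 1.90, CHAC1 1.86, BTG2 1.80, CITED2 1.80, PLK2 1.72, BHLHE40 1.64, BAMBI 1.54, KLF10 1.45, PRR5-ARHGAP8 -0.79, SLURP1 -0.74, BLOC1S1-RDH5 -0.71, YJEFN3 -0.63, PAQR6 -0.63, PAM -0.60, CPT1B -0.60, TPM2 -0.58, ENO3 -0.56 and FBXL8 -0.56 per hour. The count was 310 without the 2 h libraries, 1089 without 15 min and 712 without 0 h.

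Short-lived mRNAs, 685 genes chosen in untransfected C4-2, lost less in both knockdown series than in the control. Library scaling as the whole cause was excluded, since it would move all genes alike and the smaller of the 2 gaps between genes that fell in C4-2 and the others was 0.254 per hour. The floor of the scale as the whole cause was excluded too, since genes that started at or above the control still had a median difference of at least 0.473. These were 258 genes in the METTL3 knockdown and 382 in the YTHDF2 knockdown. For genes that started lower the floor was not tested. A weaker or later transcription block may explain the pattern, since it would touch nearly all short-lived mRNAs and the lower of the 2 shares with a less negative slope was 96.8%. Slower decay through loss of METTL3 or YTHDF2 also stays open and was not tested; m6A libraries of the control and the METTL3 knockdown were not analysed here.

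Other splits of the libraries were compared with the real ones. For T cells at 15 min, 1 h and 2 h the 10 splits of 6 libraries were too few for a share under 0.05; in each, 1 split (the real one, with 102, 3354 and 5874 genes) reached the real count, and the highest others gave 1, 0 and 0. For the T cell slope chance was excluded among splits that ignore the pairing by replicate number, with 1 of 100 splits reaching 6181 and the highest other at 4934. Splits that keep the pairing were not run for the slope. For levels only the real split reached the real count in these libraries, in each of the 4 comparisons (1 of 35 splits each). The counts were 11558 for PrEC against C4-2 (highest other 7775) and 9319 for the METTL3 knockdown (3303). They were 10050 for the YTHDF2 knockdown (3475) and 9320 for the control against C4-2 (1429). Each arm is the 4 times of 1 series, so any steady difference between series favours the real split. The control against C4-2 had this outcome without a knockdown. These level splits therefore cannot exclude chance, and they tell nothing of a new culture or of an effect of a knockdown. For slopes as many genes came from 3 of 35 splits for PrEC against C4-2 (299, highest other 10637), 3 for the METTL3 knockdown (1055, 8011), 3 for the YTHDF2 knockdown (1987, 8756) and 35 for the control against C4-2 (0 genes, limma, 1169 at an unadjusted p under 0.05; highest other 8054).

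The slope splits that called many times the real count point to a structure of the samples. They put 0 h and 15 min of one series with 1 h and 2 h of the other, so that a difference in level between series became a slope, and these splits do not decide about chance. With each series centred first, 1 of 35 splits reached the real count for the METTL3 knockdown (highest other 1027). For the YTHDF2 knockdown it was 2 (highest other 2107), for PrEC against C4-2 2 (highest other 320) and for the control against C4-2 all 35 (highest other 4). Only for the METTL3 knockdown did no other centred split reach the real count, by a margin of 1055 over 1027. Many splits mix the times unequally between the arms, so they are not like the real one and cannot exclude chance. The counts again speak only of these libraries.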

How the results depend on the processing

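The leave-out of single libraries other than replicates, the mitochondrial term and the list without immediate early members were added after the data were seen. Of 171 alternatives for counts of genes, 138 stayed within 1.5 times the count reported. For the tumour suppressor list 90 of 97 kept their side of the threshold, judged on the unadjusted limma camera p with the preset correlation alone. With an estimated correlation some of the 90 crossed it, as given for PrEC and C4-2. The 90 also include a gap that turned, the METTL3 knockdown level without the 2 h libraries (-0.0066 against 0.04). For named genes, direction and threshold side held in 2286 of 2526 checks (234 weaker, 5 stronger, 1 reversed). A check is a named gene of a comparison under an alternative, and 196 such gene results were covered. Of the T cell comparisons, only the genes named at 2 h were among them. The genes named for the earlier T cell times and for the T cell slope were not checked in this way. The knockdown correlation stayed within 1 SD of the simulations in 3 of 3. Except where fewer libraries or genes were used by construction, the cause was not tested.

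For T cells at 15 min (102 genes) the count was 42 with a pseudocount of 0.1 and 39 with a mean FPKM of 5 or more. It was 54 under quantile normalization, 174 under ribosomal protein scaling and 660 with the replicate block. Leaving out a replicate in the fit without the block gave 0 (without replicate 2, limma) to 23. At 1 h (3354) it was 2164 with a mean FPKM of 5 or more, 5848 under ribosomal protein scaling, 6199 with the block, and 1562 to 2658 without a replicate. Beyond the list calls given in the report, the block added set calls for the T cell slope of B cell markers (adjusted p = 0.050, just under the threshold, but adjusted p = 0.34 with an estimated correlation) and monocyte markers (0.0018, but adjusted p = 0.11 with an estimated correlation). It changed no other set call. Counts within other lists at 15 min, 1 h and in the slope also moved by over 1.5 times.

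For the PrEC slope the count was 579 without the 2 h libraries, and for the C4-2 slope 2120 without the 0 h and 615 without the 2 h libraries. For PrEC minus C4-2 slopes it was 187 with straight lines, 59, 50 and 23 without the 0 h, 15 min and 2 h libraries, and 196 in the fit of 8 libraries. For METTL3 knockdown slopes it was 676 with straight lines and 271, 404 and 135 without the 0 h, 15 min and 2 h libraries. For YTHDF2 knockdown slopes it was 3122 under ribosomal protein scaling, 712, 1089 and 310 without the same libraries, and 643 with the mitochondrial term. For the control against C4-2 in slope it was 2 without a filter, 2 with a mean FPKM of 5 or more, 4 under quantile normalization and 7 without the 1 h libraries. The slope of HIST1H2AG in the METTL3 knockdown turned to 0.037 without the 2 h libraries (adjusted p = 0.98).

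The tumour suppressor list in the YTHDF2 knockdown level had a gap to the other genes of 0.15 at an unadjusted p of 0.048. The gap was 0.13 with a mean FPKM of 5 or more, 0.15 under quantile normalization, 0.15 with straight lines, 0.11 without the 2 h libraries, 0.15 with the mitochondrial term, 0.12 without the control 1 h library and 0.11 without immediate early members. The unadjusted values from limma camera for these were 0.12, 0.060, 0.066, 0.12, 0.057, 0.065 and 0.18, all above the threshold. Read depth is not stated, so no limit from depth can be given for low FPKM values.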

Other observations

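Of the tests in this part, the test of a library batch that moves other genes was planned, and the others were chosen after the result was seen.

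The mRNA of YTHDF2, a protein that brings other mRNAs to decay, fell by 2.75 in T cells at 2 h, and its slope was -0.52 per hour in C4-2.

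For MYC, BTG2 and KLF10, given as examples, FPKM at 2 h was a larger share of its 0 h value in the knockdown series than in the control. MYC stood at 5.32% of its 0 h FPKM in the control, 15.0% in the METTL3 knockdown and 26.4% in the YTHDF2 knockdown. For BTG2 the values were 4.32%, 30.5% and 66.2%, and for KLF10 13.2%, 82.0% and 129%. The KLF10 value of 129% is a rise against the rest of the library, so these shares do not measure how much mRNA remained. Each value rests on 1 library per time.

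In both knockdown series S phase and G2/M phase genes were lower than in the control. Library scaling as the whole cause was excluded, since the gap between G2/M genes and the others nearest to 0 was -0.93. A difference between culture series apart from the knockdown may be the source, since the control itself differed from untransfected C4-2 by a median of -1.66 in these genes. An effect of the knockdowns stays open, as each had 1 series of cultures.

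Mitochondrially encoded features were listed at 0 in most prostate libraries and at 1589 to 10609 FPKM in a few. These were 6 features in 6 of 20 prostate libraries (PrEC at 0 h, 1 h and 2 h, the control at 1 h and 2 h, and the YTHDF2 knockdown at 0 h) and in none of 12 T cell libraries. A library batch that moves other genes as well stays open. A term for these libraries called 0.00767% of the other genes, under the bound set beforehand, but that bound took no account of power: 925 of 13046 genes had an unadjusted p under 0.05, and the term lowered the count of YTHDF2 knockdown slopes from 1987 to 643, a contrast it overlaps. Features left without an estimate in some libraries are a candidate explanation, since 0% of the 120 values lay between 0 and 1000 FPKM. The definition of these features was reworded after a first version also took in genes restricted to 1 cell type, and no biological explanation was tested.

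The control 1 h library held KRT5 at 5.83 FPKM, KRT17 at 4.64 FPKM and KRT6A at 3.70 FPKM. These values were 0.0863%, 0.0804% and 0.0877% of the PrEC means. In untransfected C4-2 the same genes were listed at 0 FPKM at every time. KRT14 stood at 7.13 FPKM in the control 1 h library, 0.136% of its PrEC mean, but untransfected C4-2 also held it (2.31 FPKM at 0 h). The source of these keratin values was not tested.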
